A study of Escherichia coli str. K-12 substr. MG1655 with 3 samples.

How the data were processed

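Total RNA of MG1655 cells carrying pHM4T, the vector with full sdsR, or the vector with nucleotides 45 to 103 of sdsR was sequenced, with 1 library per group. Per the series' design text, RNA was purified on columns of an RNeasy kit, treated with Turbo DNase, depleted of ribosomal RNA with Ribo-Zero and made into stranded TruSeq libraries, which were read as single ends on an Illumina HiSeq instrument. Per the same text and the submitters' processing notes, quality-filtered reads were aligned with Bowtie2 to a reference genome, and abundance was given by relative log expression (RLE). The authors' own screen asked for a 2-fold difference with an edgeR p-value under their threshold, per the design text. The Bowtie2 version, the genome build, the read counter and how the reads of repeated genes were treated are not given in the sources used here. Column purification of this kind can lose short RNAs, which bears on the levels of small RNAs in all 3 libraries.

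The deposited values are a normalized signal per gene, read counts that the authors divided by an RLE size factor, per the file headers and the design text. Each file holds 1 library and 4498 gene rows with a symbol, start, end and strand, and no other per-sample column was left unused. Of these rows, 4278 symbols were found in a gene table of the ASM584v2 assembly, and 4358 rows had the same start and end as there. Coordinates are printed as the files give them, all on the 1 chromosome of the strain. The values in each file were whole multiples of 1 step, which is what 1 read was worth after scaling. Dividing by the step gave whole reads for 100% of the values in each library, within a tolerance of 0.006 normalized counts. The totals were 19839427 reads for the vector, 21402390 for SdsR and 27860847 for the library labelled SdsR(45-103), with a median of 366, 417 and 538 reads per gene, and 178, 162 and 168 genes at 0. The 10 most abundant genes took 24.0%, 27.8% and 26.9% of the reads. The 22 ribosomal RNA rows and the 86 transfer RNA rows were at 0 in all libraries. Reads on the 2 strands were counted apart, since sdsR had 0 reads where the overlapping antisense gene ryeA had many. There were 55 rows that shared a symbol with another row, and 46 of them had a same-named row with identical reads in every library, mostly copies of insertion sequences, so their values are uncertain.

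Groups were taken from the titles, source names and genotypes, which match the file headers. The description field gives the names of the 2 libraries with an insert the other way round, and that naming was run as an alternative. Because the fragment's library had no reads on sdsR, its label could not be checked and it is called the library labelled SdsR(45-103). The label of the SdsR library was not settled by its sdsR reads either. They are counted over the whole row, so they cannot tell the full RNA from nucleotides 45 to 103.

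The 3 comparisons were SdsR against vector, the labelled fragment against vector, and SdsR against the labelled fragment. Ratios were log2 ratios of normalized counts plus a pseudocount of 1, which understates the ratio of low genes. Genes needed a mean of at least 10 over the 3 libraries, which 4129 passed. With 1 library per group there is no residual spread, so no count model could be tested on the recovered reads and no p-value was computed. Genes were counted by size alone, at 2-fold or more. The 95% interval of each ratio is the exact Clopper-Pearson interval of the share of reads, and compares the libraries, not the conditions. Where a library had 0 reads, the ratio was taken against the value of 3 reads. In the counts and medians sdsR has its ratio with the pseudocount, and no list median differs with the bound in its place, as sdsR is the highest member either way.

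The genes named were chosen by a rule set before the data were examined. They are sdsR, ryeA and the 5 reported targets, the 12 highest and 12 lowest genes of each comparison with the vector, and the 8 highest and 8 lowest between the libraries with an insert. These came from genes whose 3-library mean was at or above the median of detected genes, 495 normalized counts. Up to 4 members furthest from 0 were added from any described list, and a gene named in one comparison could be named in the others. The 42 gene lists were also set beforehand from general knowledge of the strain. A list's median has a 95% order-statistic interval over its genes, which are not replicates, and its percentile among 10000 random lists matched on expression in 20 bins, as a description of these libraries.

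The overlap of the comparisons with the vector was set beside 100 simulated sets of unchanged libraries that share a vector library, drawn with counting error alone or with an assumed coefficient of variation of 20% or 40%. The steps were tested on simulated data for SdsR against vector, over 4498 genes, with counting error alone and no variation between cultures. The shares below therefore do not give the rate of false calls between real cultures. All reads were recovered from the simulated values (100%). Genes raised 2.5-fold and 4-fold passed 2-fold in 96.0% and 100% of cases, genes lowered to 0.25-fold in 97.9%, genes raised 1.5-fold in 0%, and 0.38% of 3921 unchanged genes passed it.

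Alternatives were pseudocounts of 0.1 and 5, no filter or a minimum mean of 50, libraries scaled to a median ratio of 0, to equal totals or by TMM, thresholds of 1.5-fold and 3-fold, and the naming of the description field. Counting identical copies once, requiring an interval that leaves out equality and requiring an interval wholly beyond 2-fold were chosen after seeing the data. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with R 4.3.3 and edgeR 4.0.16 for the TMM factors only.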

Results

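RNA abundance was measured by strand-specific RNA sequencing in the Escherichia coli laboratory strain MG1655. The cells carried the empty vector pHM4T, or a derivative that makes an RNA from an IPTG-inducible promoter. One derivative carried the full sdsR gene, and the other carried only its nucleotides 45 to 103. SdsR is a small regulatory RNA that pairs with messenger RNAs with the help of the chaperone Hfq, and it normally accumulates late in growth under the stationary-phase sigma factor RpoS. By its title, the series is about what happens to cells when SdsR is made outside its usual growth phase. Cells were grown for 3 h, to an optical density of 1.5 to 1.7, and were given 1 mM IPTG for 10 min before harvest. There was 1 library per group and there were 3 groups, so no difference described here has a replicate check and no p-value is given. The libraries held 19839427 reads on genes for the vector, 21402390 for SdsR and 27860847 for the library labelled SdsR(45-103). Values are normalized read counts, and 1 read was worth 1.20, 1.04 and 0.801 in the 3 libraries, in that order. Of 4498 gene rows, 4129 had a mean of at least 10 over the 3 libraries and entered the comparisons. Intervals are 95% exact counting intervals of a ratio of reads. They cover counting error only, since reads were not counted by molecule, and the variation between cultures is not in them.

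The induced gene was looked at first in every library. The sdsR row, 104 nt on the minus strand of the chromosome at 1923104 to 1923207, had 16850.3 normalized counts (16158 reads) in the SdsR library. It had 0 reads in the vector library and 0 reads in the library labelled SdsR(45-103). Against the value that 3 reads would have in each library, sdsR was at least 4692-fold higher in the SdsR library than in the vector library, and at least 7012-fold higher than in the library labelled SdsR(45-103). The vector library, which has no sdsR insert, thus had no counted reads from the chromosomal gene at this stage of growth and this depth. Whether that gene was silent, or its short RNA was lost in purification or left uncounted, was not tested. Because the fragment's own library had no reads on the sdsR row either, its label rests on the submitters' title, source name and genotype and has no check in the reads. The submitters' description field names the SdsR and SdsR(45-103) libraries the other way round. The gene ryeA, which encodes an antisense RNA of 249 nt on the plus strand at 1923066 to 1923314 and spans the whole of sdsR, had 3240 normalized counts with the vector, 2817 with SdsR and 477 in the library labelled SdsR(45-103). Its log2 ratio to the vector library was -0.20 with SdsR (interval -0.28 to -0.12) and -2.76 in the library labelled SdsR(45-103) (-2.90 to -2.64).

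The 5 genes that had been reported as SdsR targets were all lower in the SdsR library than in the vector library, by 2-fold or more each. The gene tolC, which encodes the outer membrane channel of multidrug efflux pumps, was 6.39-fold lower, with 22771 normalized counts in the vector library and 3565 in the SdsR library (log2 ratio -2.67, interval -2.73 to -2.62). The gene stpA, which encodes an H-NS-like DNA-binding protein and RNA chaperone, was 5.18-fold lower, at 842 and 162. The inner membrane protein gene yhcB was 3.27-fold lower, at 4907 and 1502. The global regulator gene crp was 2.24-fold lower, at 19558 and 8738, and the mismatch repair gene mutS was 2.06-fold lower, at 4685 and 2274. The ratio of mutS came under 2-fold when the libraries were scaled to equal totals. The median log2 ratio of the 5 genes was -1.71, at the 0.015 percentile of 10000 random lists of matched expression. In the library labelled SdsR(45-103) the level of tolC was 22213, next to that of the vector library (log2 ratio -0.04, interval -0.06 to -0.01). The other targets lay below the vector there, and 1 of the 5, stpA, was at least 2-fold lower (264, log2 ratio -1.67). The median of the 5 in that library was -0.73, at the 0.22 percentile of random lists. The gene yhcB stood at 2940, crp at 13045 and mutS at 2824 (log2 ratios -0.74, -0.58 and -0.73). Between the 2 libraries with an insert, tolC was 6.23-fold lower with SdsR and yhcB was 1.96-fold lower. Whether any of the 5 was first picked as a target from these libraries is not given in the sources used here.

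**Figure D1:**
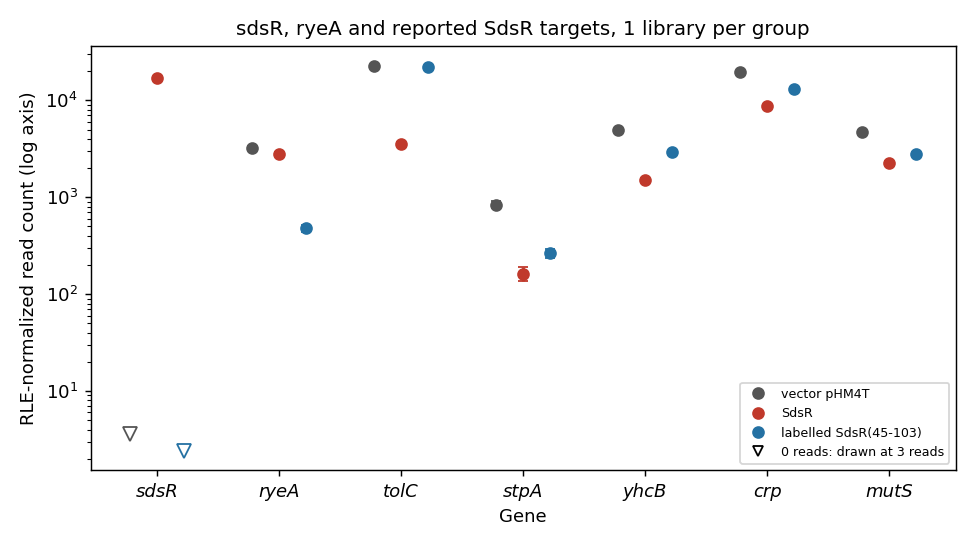
Normalized read counts (log axis) of sdsR, its antisense partner ryeA and the 5 reported targets, 1 point per library. The tolC point of the SdsR library lies at 3565, below 22771 with the vector and 22213 in the library labelled SdsR(45-103).

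The comparison of SdsR with the vector asks which transcripts differ 10 min after full-length SdsR is induced. Besides sdsR itself, the genes furthest above the vector were phoH, acs, mhpR and hmp. The gene phoH, which encodes an ATP-binding protein, was 10.7-fold higher (178 and 1926 normalized counts, interval of the log2 ratio 3.19 to 3.68). The acetyl-CoA synthetase gene acs was 8.30-fold higher (855 and 7105). The proline transporter gene putP was 7.10-fold higher, the glycine and D-alanine transporter gene cycA 5.26-fold, and the dipeptide-binding protein gene dppA 4.68-fold. The fatty acid oxidation gene fadB was 6.31-fold higher, and ugpB, for the glycerol phosphate binding protein, 5.08-fold. The regulator genes mhpR, for phenylpropionate use, and glcC, for glycolate use, were 7.62-fold and 6.92-fold higher. The flavohemoglobin gene hmp was 7.32-fold higher (1760 and 12891), and hcr, the reductase of the hybrid cluster protein, was 5.55-fold higher. Among the genes furthest below the vector, aphA, an acid phosphatase gene, was 20.8-fold lower (4211 and 201) and flu, which encodes the surface adhesin antigen 43, was 20.5-fold lower (59622 and 2906). The other 10 of the 12 lowest genes were narI, narG, narH, narJ, narK, napF, napB, napA, napH and nirB, which encode nitrate and nitrite reductases with their accessory proteins and a nitrate transporter. They were 10.1-fold to 15.3-fold lower, as in narG (24367 and 1821) and napA (47845 and 4432). In all, 197 genes were at least 2-fold higher in the SdsR library and 223 were at least 2-fold lower. With the libraries scaled to equal totals the balance turned, to 234 higher and 188 lower. The counting interval also left out equality for 193 and 219 of them, and it lay wholly beyond 2-fold for 118 and 151.

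By the gene lists fixed before the data were examined, the SdsR library stood above the vector library for the RpoS general stress response and for several lists of catabolism and nutrient uptake. Of 64 measured genes of the RpoS general stress response, 13 were at least 2-fold higher and none was lower, with a median log2 ratio of 0.65 (interval over genes 0.50 to 0.69). They included csiD (3.47-fold), ybgA (2.98-fold) and aldB (2.98-fold), besides phoH. Of 10 fatty acid degradation genes, 5 were higher and 1, the importer gene fadL, was lower, though not with equal totals (median 1.08, -0.38 to 1.82). The genes fadB, fadH (3.53-fold), fadE (2.47-fold) and fadD (2.34-fold) were among the 5. Of 43 amino acid degradation genes, 12 were higher and none was lower (median 0.43, 0.31 to 0.72), such as putA, the proline dehydrogenase gene (4.41-fold), and astC of the arginine pathway (7.03-fold). The list of CRP-activated sugar uptake holds 88 genes, among them regulators, enzymes and genes for other carbon sources such as acetate. Of these, 11 were higher and 2 lower (median 0.35, 0.17 to 0.52), with cstA, a pyruvate and peptide transporter gene, 3.51-fold higher and the maltose activator gene malT 3.11-fold lower. Of 32 nitrogen starvation genes, 7 were higher and 1 lower, or none lower with equal totals (median 0.46, 0.01 to 0.70), with argT, for the lysine, arginine and ornithine binding protein, 4.36-fold higher. Of 25 tricarboxylic acid cycle genes, 4 were higher and 1 lower (median 0.57, 0.27 to 0.68), with sdhC 2.30-fold higher and the malate oxidase gene mqo 2.12-fold lower, or under 2-fold with equal totals. The median of each of these 6 lists lay at or above the 99.99 percentile of random lists of matched expression. Those random lists ignore operons, whose genes can move together, so the percentiles may be too extreme. Some of the 6 lists also share genes, such as astC in amino acid degradation and nitrogen starvation. Optical density at harvest is given only as a range, and each group had 1 culture. Whether a difference in growth stage between the cultures, rather than SdsR, shifted these lists was therefore not tested. The same limit holds for the lists below the vector described next.

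Lists with many genes below the vector included those of translation, nucleotide synthesis and anaerobic respiration. All 54 measured ribosomal protein genes lay below the vector library, 4 of them by at least 2-fold (median log2 ratio -0.76, interval over genes -0.84 to -0.65), such as rpsT (2.59-fold) and rpsU (2.55-fold). With equal totals or TMM scaling 2 of them were past 2-fold. Of 38 genes of translation factors and tRNA synthetases, 37 lay below and 3 by at least 2-fold (median -0.42, -0.49 to -0.24), with infA, for an initiation factor, 3.69-fold lower. Of 32 purine and pyrimidine synthesis genes, 13 were at least 2-fold lower and none was higher, or 1 with equal totals (median -0.86, -1.12 to -0.54), such as purE (3.81-fold), pyrD (3.55-fold) and purM (2.85-fold). Of 60 anaerobic respiration and fermentation genes, 25 were lower and 2 higher (from 1 to 4 over the scalings and pseudocounts), and the median was -0.05 (-1.58 to 0.29), since the list's other members lay near or above 0. Among 40 measured small RNAs, 7 were lower and sdsR alone was at least 2-fold higher (median -0.20, -0.52 to -0.07). The small RNA sgrS, which answers sugar-phosphate stress, was 4.06-fold lower (922 and 226), mgrR 3.55-fold and isrC 13.3-fold. The sigma E list of envelope stress had 3 of 32 genes higher and none lower (median -0.06, -0.20 to 0.17), namely rpoE, the sigma factor itself (3098 and 11158, 3.60-fold), rseA, its anti-sigma factor (3.16-fold), and eptB (2.40-fold). Of 26 genes of Hfq, RNA chaperones and RNA decay, 3 were lower and none higher (median -0.21, -0.73 to -0.02), namely stpA, the ribonuclease gene rnb (2.18-fold) and the helicase gene deaD (2.16-fold). Of 81 amino acid biosynthesis genes, 2 were lower, cysM (2.94-fold) and argC (2.05-fold, or under 2-fold with equal totals or a pseudocount of 5), and 1, asnA, was higher (3.22-fold; median -0.09, -0.16 to 0.04).

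The comparison of the library labelled SdsR(45-103) with the vector asks what the 59 nt fragment does without the part of the RNA before nucleotide 45. It takes the fragment to be present, though no sdsR reads showed it. The genes furthest above the vector were hcr and hcp, of the hybrid cluster protein system, at 7.92-fold and 7.35-fold (hcp at 596 and 4390 normalized counts), and hmp at 5.21-fold. The genes ynfF, ynfG, ynfH and ynfE of a selenate reductase operon were 4.90-fold, 4.78-fold, 4.23-fold and 3.79-fold higher. The remaining 5 of the 12 highest were dcuB, a C4-dicarboxylate carrier gene (3.44-fold), ydhV (2.89-fold), ydhY (2.54-fold), ytfE, for an iron-sulfur cluster repair protein (2.46-fold), and tdcA, the activator of threonine breakdown (2.42-fold). On the low side were 7 genes of sulfur uptake and cysteine synthesis that lay within 2-fold of the vector with full SdsR. The sulfate permease genes cysU, cysW, cysP and cysA were 22.6-fold, 19.3-fold, 16.7-fold and 16.0-fold lower, the sulfite reductase gene cysJ 13.7-fold (10336 and 756) and cysD 12.2-fold. The transport gene yeeE was 18.9-fold lower (6045 and 320). With them stood flu, 23.4-fold lower (59622 and 2546), and 4 genes of nitrate reductases, napB, narH, narI and napF, 11.4-fold to 14.1-fold lower. In all, 58 genes were at least 2-fold higher and 163 at least 2-fold lower in this library than in the vector library. The counting interval also left out equality for 53 and 161 of them, and it lay wholly beyond 2-fold for 20 and 125.

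Of the fixed lists, those of anaerobic respiration and of amino acid biosynthesis held the most genes that were at least 2-fold lower than the vector in the library labelled SdsR(45-103). Of 60 anaerobic respiration and fermentation genes, 22 were at least 2-fold lower and 1, dcuB, higher, or 2 with equal totals (median log2 ratio -0.17, interval over genes -1.01 to 0.20). Of 81 amino acid biosynthesis genes, 9 were lower, all of them cys genes and cysM alone of them also with full SdsR, and 1, the asparagine synthetase gene asnA, was higher (median 0.02, -0.13 to 0.10). All 54 ribosomal protein genes lay below the vector, 2 of them, rpsT (3.99-fold) and rpsU (2.31-fold), by at least 2-fold (median -0.47, -0.54 to -0.39). Of 64 RpoS genes, 5 were higher and none lower (median 0.39, 0.26 to 0.46), such as yodD (2.35-fold), ybgA (2.34-fold) and glgS (2.12-fold). Of 32 purine and pyrimidine synthesis genes 3 were lower (median -0.26, -0.48 to -0.14), namely pyrL, pyrD and upp, the last not with equal totals. No fatty acid degradation gene reached 2-fold (median -0.16, -0.41 to 0.17). Of the 88 genes of the CRP list, 62 lay above the vector, none of them by 2-fold or more (median 0.19, 0.12 to 0.23). The 2 that were at least 2-fold lower were nagE, for the N-acetylglucosamine transporter (4.38-fold, 8642 and 1970.5), and the maltoporin gene lamB (3.42-fold, 21846 and 6383). Single genes in other lists that were lower included icd, for isocitrate dehydrogenase (5.35-fold, 52144 and 9755), the disulfide oxidoreductase gene dsbA (5.36-fold, 5951 and 1110.2) and hfq itself (3.19-fold, 8618 and 2701). With full SdsR the levels of nagE, lamB, icd, dsbA and hfq were 9073, 23923, 62818, 4496 and 7783. Amino acid degradation had 1 higher, or 2 with equal totals, and none lower (median 0.25), nitrogen starvation none higher and 1 lower (median 0.11), and the tricarboxylic acid cycle 1 of each (median 0.12). The small RNAs had 2 lower, isrC and ryeA, and none higher, or 1 with equal totals (median -0.12), translation factors 1 lower, infA, though not with equal totals (median -0.20), and the sigma E list no gene past 2-fold (median -0.12). The list of Hfq, RNA chaperones and RNA decay had 2 lower, hfq and stpA (median -0.13). The RpoS and ribosomal protein medians lay in the same direction as with SdsR (0.65 and -0.76 there). The fatty acid degradation median did not (1.08 with SdsR). Whether a difference in growth stage from the vector culture had a part in these shifts was not tested here either.

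The direct comparison of the 2 libraries with an insert asks what the full RNA adds to its 45 to 103 part. It takes that part to be present, though no sdsR reads showed it. With full SdsR, 132 genes were at least 2-fold higher and 57 at least 2-fold lower than in the library labelled SdsR(45-103). The counting interval also left out equality for 132 and 51 of them, and it lay wholly beyond 2-fold for 97 and 24. With no filter on low values 86 were lower. Those furthest above, after sdsR, were cysU (18.8-fold), cysP (18.6-fold), cysJ (14.6-fold), cysW (13.2-fold), yeeE (12.8-fold), cysD (12.3-fold) and phoH (12.2-fold). Those furthest below were tolC (6.23-fold), yfcC, a putative transporter gene (3.99-fold, 326 and 1305), artI, for an arginine-binding protein (3.35-fold, 1275 and 4277), tdcA (2.85-fold), aphA (2.77-fold), malT (2.75-fold), plaP, a putrescine importer gene (2.63-fold), and the outer membrane assembly gene tamA (2.53-fold). Of these, artI, malT and tamA stood near the vector level in the library labelled SdsR(45-103), with log2 ratios to the vector of 0.11, -0.18 and -0.16, and at -1.64, -1.64 and -1.49 with SdsR. Fatty acid degradation had 5 of 10 genes higher with full SdsR (median log2 ratio 1.06, interval over genes -0.18 to 1.59). Amino acid biosynthesis had 8 of 81 higher, and all 8 were cys genes (median -0.03, -0.07 to 0.04). Nitrogen starvation had 8 of 32 higher (median 0.30, 0.02 to 0.61), the CRP list 10 of 88 higher and 2 lower (median 0.13, 0.09 to 0.25), and purine and pyrimidine synthesis 5 of 32 lower (median -0.53, -0.63 to -0.23). The ribosomal protein genes had none past 2-fold (median -0.22, -0.28 to -0.18), and the 60 anaerobic genes had 3 lower (median -0.06, -0.22 to 0.02). The RpoS list had 3 of 64 higher (median 0.27, 0.20 to 0.37). Amino acid degradation had 7 of 43 higher and 1 lower (median 0.21, 0.02 to 0.44). The tricarboxylic acid cycle had 4 of 25 higher (median 0.19, -0.02 to 0.41), and the sigma E list 3 of 32 (median 0.13, -0.02 to 0.33).

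Many of the genes that were low with one insert were also low with the other. There were 97 genes at least 2-fold lower than the vector in both libraries, and 34 at least 2-fold higher in both. Independent lists of these sizes would share 8.80 and 2.77 genes. Both comparisons use the same vector library, so 100 sets of libraries with no difference between groups were simulated against a shared one. With counting error alone they shared 0.750 lower and 2.61 higher genes on average (at most 3 and 7). With an assumed variation between cultures of 20% the averages were 6.93 and 17.6 (at most 15 and 35), and with 40% they were 144 and 215. The 97 lower genes thus lay above all sets with 20%, and the 34 higher genes did not. The 215 exceeds the 58 genes that were higher at all in the library labelled SdsR(45-103). Independent variation of 40% over all genes is therefore argued against, though joint shifts are not. The true variation between cultures is unknown here and the single vector library cannot be split, so the overlap may come in part or in whole from the shared vector library. The simulation cannot say how much. It varied each gene independently, so joint shifts of whole operons are not in it. In each setting it also shared more higher than lower genes on average, the reverse of the data. Only ycgZ, a small gene of biofilm regulation, was at least 2-fold higher with SdsR and at least 2-fold lower in the library labelled SdsR(45-103), at 40.7, 89.7 and 16.0 normalized counts for vector, SdsR and the labelled fragment. No gene had the reverse pattern. Independent lists would give 7.78 and 3.13 such genes, and the simulated libraries gave 0 and 0 on average with counting error alone, 0.03 and 0 with 20% and 6.33 and 6.76 with 40%. The gene ycgZ is outside the rule for named genes and was named because the count was 1.

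**Figure D2:**
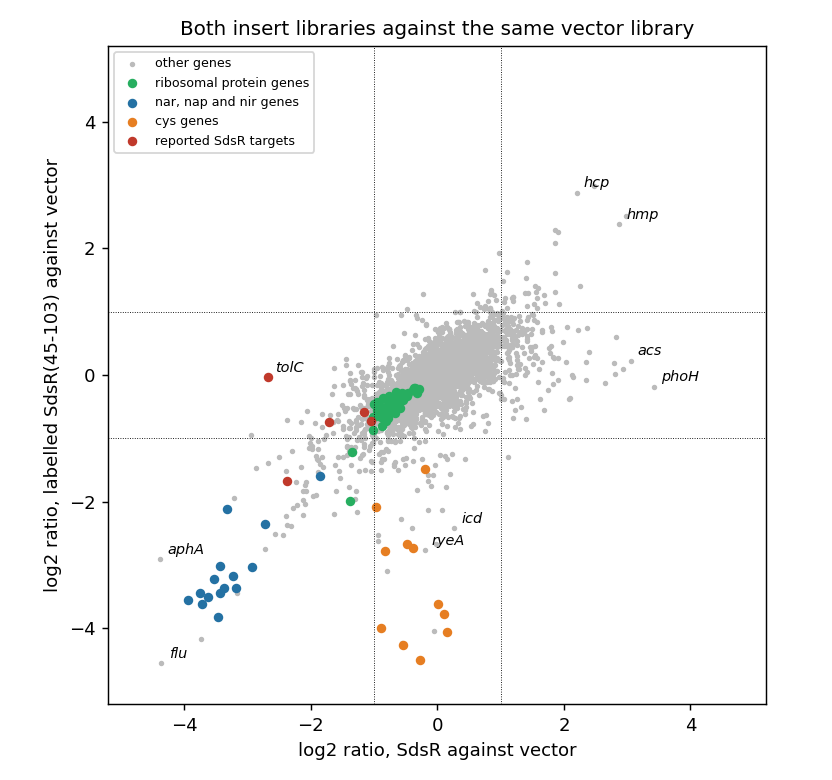
Log2 ratio to the vector library with SdsR (horizontal axis) and in the library labelled SdsR(45-103) (vertical axis), 1 point per gene with a mean of at least 10, without sdsR, with dotted lines at 2-fold and colours for ribosomal protein, nitrate and nitrite reductase, cysteine and target genes. Genes such as flu and narG lie low on both axes, tolC is low on the horizontal axis only, and cysU and cysP are low on the vertical axis only.

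The rest of the fixed lists are given by their median log2 ratios to the vector, first with SdsR and then in the library labelled SdsR(45-103), with the genes at least 2-fold apart. Among lists of stress, no gene reached 2-fold in either for heat shock (medians 0.13 and 0.06 over 30 genes), the SOS response (-0.10 and -0.01 over 31), phage shock (0.03 and 0.09 over 7) and toxin-antitoxin pairs (-0.08 and -0.05 over 41). The OxyR and SoxRS list had none and 1 lower (0.07 and 0.12), and the Rcs and capsule list none and 1 lower (0.09 and -0.11). The Cpx list had 3 higher with SdsR, and 2 higher and 2 lower in the other library (0.05 and -0.05), with the ribosome hibernation factor gene raiA higher in both (33709, 77138 and 79140 normalized counts for vector, SdsR and labelled fragment). Osmotic stress genes had 3 higher, and 1 lower (0.20 and 0.13), and cold shock genes 1 higher and 1 lower, and 1 higher (-0.22 and -0.09). Genes of phosphate starvation had 2 higher and 1 lower, and none (0.15 and -0.16), and PhoPQ and magnesium genes 2 lower and 3 lower (-0.49 and -0.45). Iron uptake under Fur had 2 higher and 3 lower, and 1 lower (-0.15 and -0.03). Cryptic prophage genes had none, and 2 higher (0.03 and 0.03), and the sdsR neighbourhood had sdsR alone higher and ryeA alone lower (0.02 and 0.01). Some of these counts moved by over 1.5 times. With equal totals and SdsR, the OxyR and SoxRS list and the toxin-antitoxin list had 1 higher each and the Fur list 1 lower, and the Cpx list had 1 lower in the other library. With a pseudocount of 5 the Fur list had 1 higher and the phosphate list none lower with SdsR, and the prophage list had 1 higher in the other library.

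Among lists of the cell surface and motility, flagella and chemotaxis genes had 2 lower and 3 lower (medians -0.21 and -0.18 over 53 genes), with the master regulator genes flhC (3.09-fold and 4.56-fold) and flhD (2.47-fold and 3.90-fold) lower in both libraries. Curli and biofilm genes had 5 lower and 1 higher with SdsR, and flu alone lower in the other library (-0.15 and 0.10). Outer membrane porins and transporters had 4 lower and 1 higher, the porin gene ompW (2.17-fold), and 1 lower, lamB (-0.25 and -0.18). Multidrug efflux had 4 lower and 2 lower (-0.24 and -0.13). The gene tolC is in these last lists and among the targets. Peptidoglycan and lipopolysaccharide synthesis had 2 lower and none (-0.27 and -0.17), fatty acid and phospholipid synthesis none in either (-0.26 and -0.10), and protein secretion 1 lower and none (-0.30 and -0.18). Cell division and elongation had 2 lower, yhcB and slmA, and 1 lower, slmA (-0.14 and -0.08), where slmA came under 2-fold in both libraries with equal totals. Mismatch and other DNA repair had 1 lower in each (-0.25 and -0.06), and RNA polymerase and transcription 2 higher and 2 lower, and none (-0.28 and -0.15). Ribosome hibernation and stringent response had 1 higher and 1 lower, and 1 higher (-0.16 and -0.13). Lists share genes, so 1 gene can count in several. The gene raiA is the higher gene of this list and of cold shock in both libraries, besides the Cpx list. In the library labelled SdsR(45-103), osmB is the lower gene of both the Rcs and the osmotic list. With SdsR, rpoE counts in the sigma E and the RNA polymerase lists. No gene of respiration and ATP synthase (-0.20 and -0.06) or of glycolysis and the pentose phosphate pathway (0.18 and 0.15) reached 2-fold. With libraries scaled to equal totals the medians of the labelled fragment's library for cell division and elongation and for respiration and ATP synthase came out on the other side of 0. Some counts of genes moved by over 1.5 times there too. With equal totals and SdsR, the lower genes were 2 for outer membrane porins and transporters. Of the 4 lower there before that scaling, phoE, fadL and pldA each came under 2-fold in some alternative. Equal totals also gave 1 lower with SdsR for peptidoglycan and lipopolysaccharide synthesis, 1 for RNA polymerase and none for DNA repair. The higher genes with SdsR were then 2 for curli and biofilm and 2 for ribosome hibernation. With a pseudocount of 5, curli and biofilm had 3 lower with SdsR and multidrug efflux had 1 lower in the other library.

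**Figure D3:**
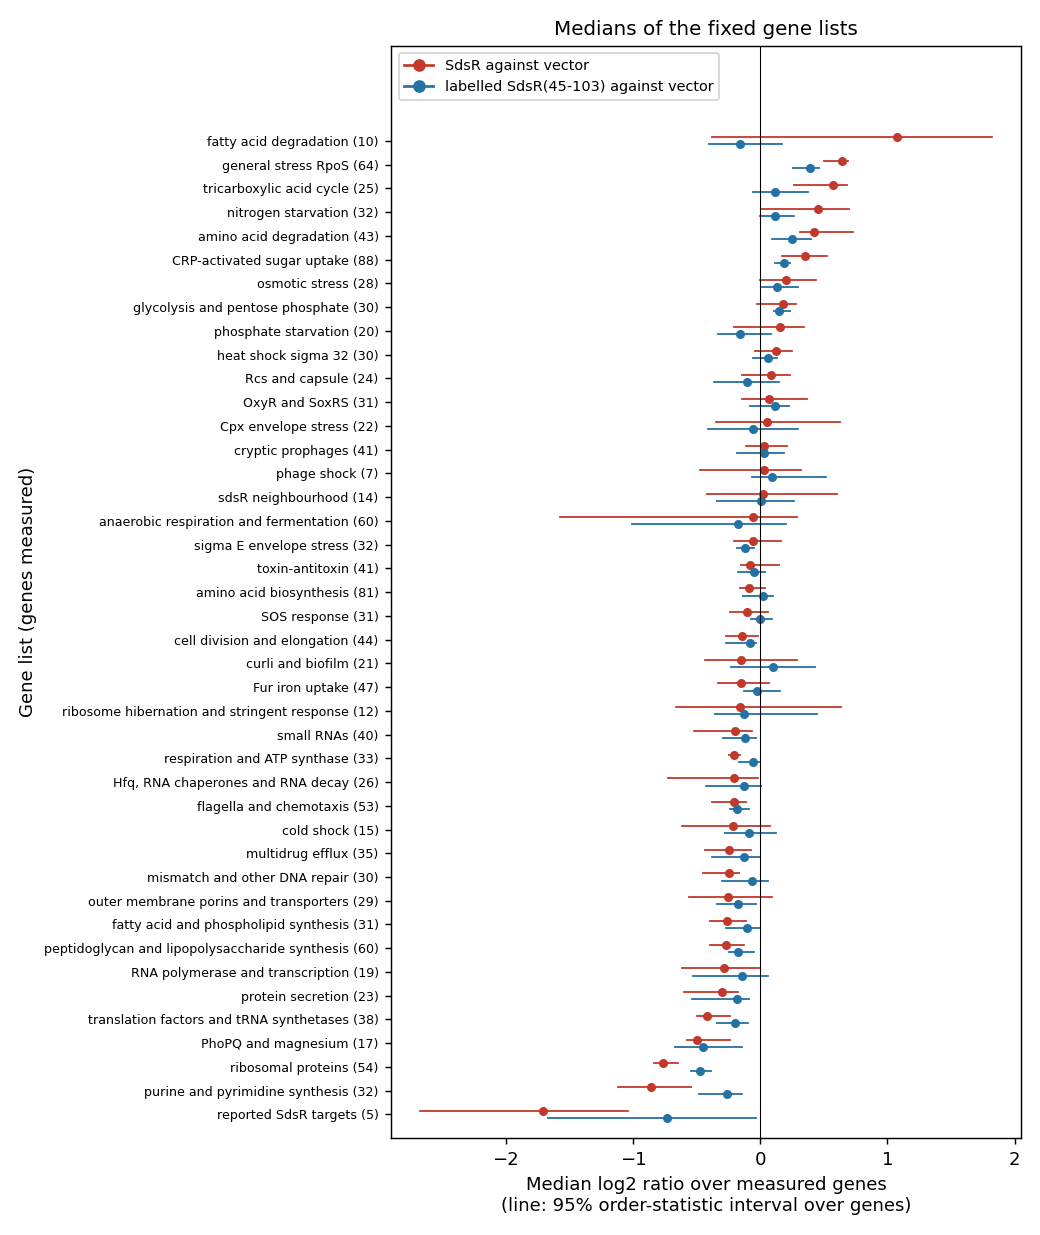
Median log2 ratio to the vector library over the measured genes of each of the 42 fixed lists, with SdsR and in the library labelled SdsR(45-103), with the number of genes in brackets and lines for the 95% interval over genes (the full range for the 5 targets). The targets, purine and pyrimidine synthesis and ribosomal proteins lie lowest with SdsR, at -1.71, -0.86 and -0.76, and fatty acid degradation lies highest, at 1.08.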

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

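No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out in turn. Alternatives that count identical copies once or use the counting interval were chosen after seeing the data. No scaling tried moved the median of all genes by over 0.1. The counts of genes moved most often with the threshold, by its construction. At 1.5-fold, SdsR against vector gave 562 higher and 571 lower genes, the labelled fragment against vector 281 and 440, SdsR against the labelled fragment 315 and 198, and both inserts against vector 189 and 286. At 3-fold these were 53 and 82, 12 and 74, 58 and 7, and 8 and 41. When the counting interval had to lie wholly beyond 2-fold, the higher genes were 118 for SdsR, 20 for the labelled fragment and 16 for both, and 24 were lower between the inserts. With no filter on low values, 86 genes were lower between the inserts and 52 were higher with both, and with a minimum mean of 50, 34 were higher for the labelled fragment. These follow from the number of low genes compared. With the libraries named by the description field, the higher genes were 58 for SdsR and 197 for the labelled fragment, with 57 higher and 132 lower between them, by construction. The other counts, including all under the pseudocounts, the 3 scalings and identical copies counted once, stayed within 1.5 times, though with equal totals SdsR against vector gave 234 higher and 188 lower genes (55.5% higher, against 46.9%).

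With equal totals, where the vector library has the largest total of normalized counts before scaling, the median log2 ratio of RpoS genes was 0.74 with SdsR and 0.48 with the labelled fragment, and that of ribosomal protein genes was -0.38 with the labelled fragment. The level of sdsR was 17932 and that of ryeA 2998 in the SdsR library. The medians of cell division and elongation (0.011) and of respiration and ATP synthase (0.032) in the library labelled SdsR(45-103) changed sign, by construction, since this scaling moved the median of all genes there to 0.0889. Of 132 named genes past 2-fold for SdsR, 21 came under it in some alternative, among them mutS, fadL, mqo, argC and slmA, as did 6 of 77 for the labelled fragment, among them upp, slmA and infA, and 5 of 90 between the inserts. At these depths 1 read was worth at most 1.20 normalized counts, so genes with means near 10 rest on few reads. The variation between cultures was not measured.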

Other observations

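Several gene groups not described so far stood apart, and they and the tests below were all chosen after the results were seen. Downstream of flu, the genes yeeR (2159, 239 and 197 normalized counts for vector, SdsR and labelled fragment) and yeeS (293, 49.0 and 50.5) were low with flu in both libraries with an insert, as was the small RNA gene isrC just upstream (261, 18.8 and 13.6). The 3 genes flu, yeeR and yeeS had median log2 ratios to the vector of -3.17 with SdsR and -3.45 with the labelled fragment. Between the 2 libraries with an insert their median was 0.19. None of the 3 libraries was taken before IPTG, so whether this locus already differed between the cultures then was not tested. Nitrate-repressed anaerobic genes, 20 in number and including the frd, dms, ynf and ydh operons, all lay above the vector with both inserts, 10 of them by at least 2-fold with SdsR and 11 with the labelled fragment. The 9 ssu and tau genes of sulfonate use, which Cbl activates, had a median of 0.05 with the labelled fragment, where cbl itself was 2.98-fold lower.

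The lac repressor gene lacI had 550465 normalized counts with the vector, 407139 with SdsR and 437980 in the library labelled SdsR(45-103), against 29368, 48015 and 36881 for lacZ. These levels of lacI cannot be assigned to the chromosome or a plasmid, since the plasmid's sequence was not used here.

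The 15 nitrate-activated genes of the nar, nap and nir operons were at least 2-fold lower with both inserts, at median log2 ratios of -3.43 and -3.37. The choice among the 4 scalings tried does not account for this, since the median nearest to 0 over them and both comparisons was -3.28. Each left the median of all genes within 0.1 of 0, so none could have closed a gap of this size. A lower nitrate signal in both insert cultures is a hypothesis that the 20 nitrate-repressed genes leave open, the lower of their medians being 1.07, but that list was drawn up after the results were seen and 7 of its genes were already among the highest of the labelled fragment. Without those 7, the medians of the other 13 were 0.69 and 0.68. The genes hcr, hcp and hmp are in neither list and were higher with both inserts. Their log2 ratios were 2.47 and 2.99, 2.20 and 2.88, and 2.87 and 2.38, and were not weighed against a lower nitrate signal. The inserts may have lowered that signal, through the 45 to 103 sequence that both carry, or the vector culture may have stood apart for reasons of growth. These cannot be told apart, as there was 1 vector culture. The 2 insert libraries lay alike for the 15 nitrate-activated genes (median between them -0.11), which either would give.

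The 11 cysteine genes were all at least 2-fold lower than the vector in the library labelled SdsR(45-103), with a median log2 ratio of -3.61, and none was with SdsR, where 8 of them lay below the vector by less (median -0.39, interval -0.89 to 0.10), while cysM, not among them, was lower with both inserts (-1.56 and -1.51). The choice among the 4 scalings, whose shifts were likewise too small to close the gap, left the median nearest to 0 at -3.52. Loss of reads at 1 place in the genome is argued against by the 2 loci over 100 kb apart that hold these genes, or 6 with the other CysB-activated genes. Lower activity of CysB, the activator of these operons, in that culture is a candidate explanation, since 6 other CysB-activated genes, sbp, cbl, ydjN, yeeE, yeeD and yciW, had a median of -2.57, or -2.53 without yeeE, which was already among the lowest genes. Whether the fragment or another feature of that 1 culture lowered it stays open, as no second culture was analysed here.

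The library labelled SdsR(45-103) had no sdsR reads although its insert lies within that row. Under the naming of the description field the 0 reads would belong to the full RNA instead, so an exchange of the 2 insert libraries leaves the absence in place, and it was not tested further. Loss of short RNAs in library preparation may account for it, and could not be decided, since the 5 annotated non-coding RNAs of 59 nt or less had only 58 reads there in all and their true levels are unknown. Cells holding the empty vector cannot be told apart from it either, as the log2 ratio of ryeA to the vector library, -2.76, has no second vector library to be judged by. The authors' rule for counting reads on a gene is not given in the sources used here, so its part in the 0 was not tested.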
